A study of Saccharomyces cerevisiae with 20 samples.

How the data were processed

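Total RNA of 5 strains (WT and disomes V, X, XIV and XVI, W303 background) at 0, 5, 15 and 30 min at 37 °C was compared with a common WT reference from 25 °C on 20 2-colour Agilent arrays, 1 per strain and time. Per the labels, RNA was extracted with acid phenol and labelled with an Agilent QuickAmp kit, the sample in Cy3 and the reference in Cy5, and per the submitters' processing notes the images were read with Agilent Feature Extraction 10.5.1.1. No paper was used. The comparisons, tests, gene lists, rule for naming genes and most alternatives were fixed before the data were examined.

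The deposited scanner files hold, per the file headers, the median spot intensity and median background intensity of each channel, net intensities with background subtracted and no dye normalization, and processed intensities with background subtracted and dyes normalized. They also hold, per the file headers, a log2 ratio of red over green processed signals, and other columns of spot flags coded 0 or 1 (saturation, outliers, signal well above background). The deposited series table of values gives a log2 value per probe and array, 6248 probes. Its header states neither scale nor direction, and both were read from the values: it correlated with the scanner log2 red over green at r between 0.847 and 1.00 by array. Its column medians ran from −0.23 to 0.34, so its columns were not centred on 0. The files are an export of the Feature Extraction spot table without its header block, so protocol settings, slides and scan dates are unknown.

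Each array held 13048 spots, of which 12512 were gene probe spots: 6256 probes with 2 spots each. These matched 6231 open reading frames, 15 of them with 2 probes, and 10 probes had no open reading frame name. The RefSeq table of locus tags and symbols supplied names for 5752 open reading frames, and 479 were not in it. No coordinates are printed, because the sources used here do not give the genome build. The filter, signal well above background in Cy3 on at least 4 arrays, kept all 6231 genes, and the same filter on Cy5 also kept 6231, so neither it nor its omission changed anything.

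Computation used R 4.3.3 with limma 3.58.1 and data.table version 1.17.8. Median spot intensities were corrected with the normexp method (offset 50) using median background, then normalized within arrays by loess, with no scaling between arrays. Mean spot signals had been planned, but the files give only medians. Spots were averaged per probe and probes per open reading frame. The plan wrote the ratio as Cy3 over Cy5, sample over reference. Cy5 over Cy3 was used instead, after the values were seen, because the value table runs that way and the duplicated chromosomes stood out in Cy5.

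Heat was tested with limma's lmFit and eBayes on all 20 arrays with strain and time as additive terms, where the 5 strains serve as replicates of each time. Each disome was tested against WT in the same fit, where the 4 times serve as replicates, and the 4 disomes were also tested as a group. In the gene counts, genes on the duplicated chromosome were counted apart, whereas the list counts and camera kept them. The response difference came from a fit that adds the interaction of time with aneuploidy. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05, and a 2-fold count is given beside each. Where genes had missing values, contrasts were fitted exactly as coefficients. The dosage of a chromosome on an array was the median log2 ratio of its genes minus that of all other genes, tested by a two-sided exact permutation of 4 against 16 arrays. The response correlation compared the response of each disome with that of WT. The baseline resemblance compared the unheated difference of a disome from WT with the mean 15 min response of the other 3 disomes.

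The 24 gene lists, written from general knowledge of yeast biology, were Hsf1 chaperones, Msn2/4 general stress, trehalose and glycogen, cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, proteasome, unfolded protein response, oxidative stress defence, cell wall integrity, iron regulon, phosphate regulon, Gcn4 amino acid synthesis, methionine and sulfur, glycolysis, TCA cycle and respiration, ergosterol synthesis, G1/S cell cycle, daughter cell separation, histones, a-specific, alpha-specific and haploid-specific genes, and sporulation genes. The last 4 serve as markers of cell type. HSP150 of the cell wall list could not be matched to a probe. Lists were tested with camera on the 5718 genes with values on all 20 arrays, with a preset correlation of 0.01 and with an estimated one, adjusted over the 24 lists in each contrast.

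Genes were named by a fixed rule. For heat it named the 6 largest rises and falls at 15 min and the 3 largest each way at 5 and 30 min, moved the same way in all 5 strains. For each disome it named the 3 largest each way off the duplicated chromosome, for all disomes the 6 largest each way with 1 sign in all 4, and for response differences the 4 largest each way. Of each list it named up to 4 members with the smallest adjusted p, and always HSP104, SSA4, HSP82, HSP12, HSP26, CTT1, BTN2 and HSP42. Dubious open reading frames were not named. For genes saturated in Cy5 on every array of a group, a lower bound is given where no array of the other group was saturated, and otherwise no size.

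The procedure was tested on simulated data of 5718 genes with 200 changed by known amounts, 50 per size. For heat at 15 min it recovered 52, 92, 98 and 100% of changes of 1, 2, 3 and 4 log2 units and called 13 unchanged genes. For disome X it recovered 46, 72, 98 and 100% and called 9, and for the response difference at 15 min 0, 16, 44 and 68% and called 2. The simulated noise was independent between genes and equally large on all arrays. On the real arrays, quality weights estimated from the residuals ran from 0.061 to 4.27, so these rates may not hold for the real data.

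Alternatives fixed beforehand were median centring, scaling between arrays, Agilent's processed signals, normexp offset 10, the value table, no filter, a strict filter (5493 genes), Cy3 alone, trend and robust moderation, the brightest probe, fits without or with random blocks, only the arrays compared, leaving out each strain or time, and other times for the correlations. Alternatives chosen after seeing the data were Cy5 alone, Cy3 over Cy5, array quality weights, leaving out the 5 dim or noisy arrays, and each of 2 sets of strains alone (WT, V and XVI; X and XIV). Overlaps between comparisons that share control arrays are not reported.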

Results

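Gene expression was followed through a heat shock in 5 strains of budding yeast of the laboratory background W303. They were a wild type (WT) and 4 disomic strains, which are haploid cells carrying an extra copy of chromosome V, X, XIV or XVI. Each strain was sampled before heating (0 min) and after 5, 15 and 30 min at 37 °C, with 1 array per strain and time and 20 arrays in all. Every array paired the sample with a common reference, wild-type RNA from cells at 25 °C. The comparisons address how the strains responded to heat, how each disomic strain differed from WT, and whether the disomic strains responded as WT did. Nothing in the labels says that the cultures were grown independently, so the p-values measure the spread between these samples, which may be partly technical.

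Median net Cy5 intensity ran from 88.5 scanner units (WT at 30 min) to 11809 (disome X at 30 min), and median net Cy3 intensity from 116 (WT at 15 min) to 4492 (disome X at 15 min). The number of arrays limits the precision, and 5 arrays were dim or noisy: WT at 15 and 30 min, disome V at 0 and 30 min, and disome XVI at 15 min. On WT at 15 min, 76.2% of gene spots in Cy5 and 69.7% in Cy3 stood well above background. Mitochondrially encoded genes, 23 of them, had a median log2 Cy5/Cy3 of 5.91 in disome V at 0 min, 4.07 in disome XVI at 15 min, 3.10 in disome V at 30 min and 2.78 in WT at 30 min, and at most 1.40 on the other 16 arrays. The Cy3 channel fell into separate profiles. Arrays of disomes X and XIV correlated with one another at a mean r of 0.990 across genes. With the arrays of WT, disome V and disome XVI, other than WT at 15 and 30 min, they correlated at a mean of 0.947. The Cy3 channel of WT at 15 and 30 min correlated with that of all other arrays at means of only 0.59 and 0.80. Both arrays enter every comparison of a disome with WT.

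**Figure D1:**
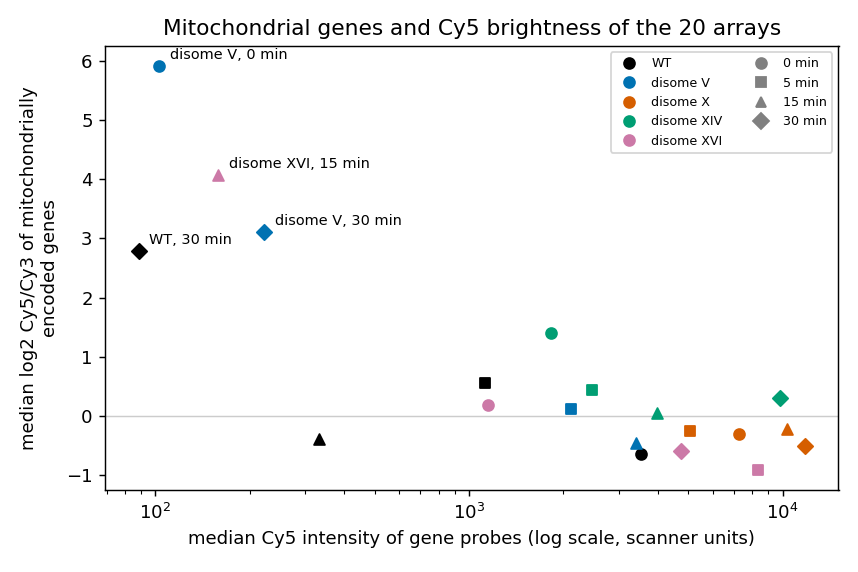
Each point is 1 of the 20 arrays, with its median Cy5 intensity over gene probes (scanner units, log scale) against the median log2 Cy5/Cy3 of 23 mitochondrially encoded genes; colour gives the strain and marker the time at 37 °C. The 4 arrays named in the plot lie between 2.78 and 5.91, and the other 16 lie at or below 1.40.

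The labels place the sample in Cy3 and the reference in Cy5, which opposes the direction used here: every signed value is Cy5 over Cy3, the orientation of the deposited value table. With the dyes of the labels every sign turns, each count of rises becomes a count of falls, and the sizes stay. On the 16 disomic arrays the values oppose the labels: the duplicated chromosomes stood out by 0.49 to 1.19 in Cy5 alone and by a mean of 0.00800 (SD 0.0525, n = 4 strains) in Cy3 alone. On the heated WT arrays, 45 Hsf1 and Msn2/4 genes had a median response of 2.39, 1.89 and 1.60 at 5, 15 and 30 min in Cy5 alone and of −0.0161, 0.73 and −0.16 in Cy3 alone. The WT array at 0 min, like its reference unheated WT, has no such check. Arrays of different samples correlated as low as −0.36 across genes before loess normalization (WT and disome XIV, both at 0 min). After it the lowest was −0.21 (WT and disome V, both at 0 min). Before loess the ratio rose with brightness on that WT array (Spearman 0.42) and fell on that of disome XIV (−0.33). The disome V array is a dim or noisy one. These correlations therefore cannot decide, and for WT at 0 min the direction is not settled. The words rose, fell, higher and lower therefore refer to Cy5 relative to Cy3.

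Genes of the duplicated chromosome were higher than the rest of the genome on all 16 disomic arrays, which checks the strain labels. On the 4 disome V arrays the median log2 Cy5/Cy3 of 285 chromosome V genes exceeded that of all other genes by 0.91 ± 0.23 (SD, n = 4), against −0.02 ± 0.05 on the other 16 arrays, a 1.91-fold difference. The 381 genes of chromosome X stood 0.73 ± 0.03 above the rest in disome X and 0.01 ± 0.04 elsewhere, a 1.65-fold difference. The smallest step belonged to chromosome XIV, whose 419 genes stood at 0.39 ± 0.09 in disome XIV and −0.07 ± 0.05 elsewhere, 1.38-fold. Chromosome XVI, with 492 genes, stood at 0.74 ± 0.40 in disome XVI and −0.06 ± 0.03 elsewhere, 1.74-fold. Each difference had a two-sided exact permutation p of 0.000206 (n = 4 against 16), the smallest that the 4845 splits of the arrays can give, and the same value after Benjamini-Hochberg adjustment over the 4 tests. The 4 arrays are time points of a single strain, so this p treats repeated samples of a strain as independent.

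The labelled chromosome ranked highest of all 16 on 16 of 16 disomic arrays, and no unlabelled chromosome moved by more than 0.32 on any array. Between 75.4% (XIV) and 97.9% (V) of the genes on a duplicated chromosome had a positive difference from WT. In limma's fit 49 of the 285 chromosome V genes passed the threshold and were higher, as were 116 of 381 on X, 117 of 419 on XIV and 79 of 492 on XVI, while 2, 8 and 1 genes of X, XIV and XVI passed and were lower. The chromosome XVI step rested partly on the dim array at 15 min, where it was 1.33, and the difference without that time was 0.61. Measured in Cy5 alone the differences were 1.17 for V, 0.74 for X, 0.49 for XIV and 1.19 for XVI, and in Cy3 alone they were −0.06, 0.00, 0.06 and 0.02.

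**Figure D2:**
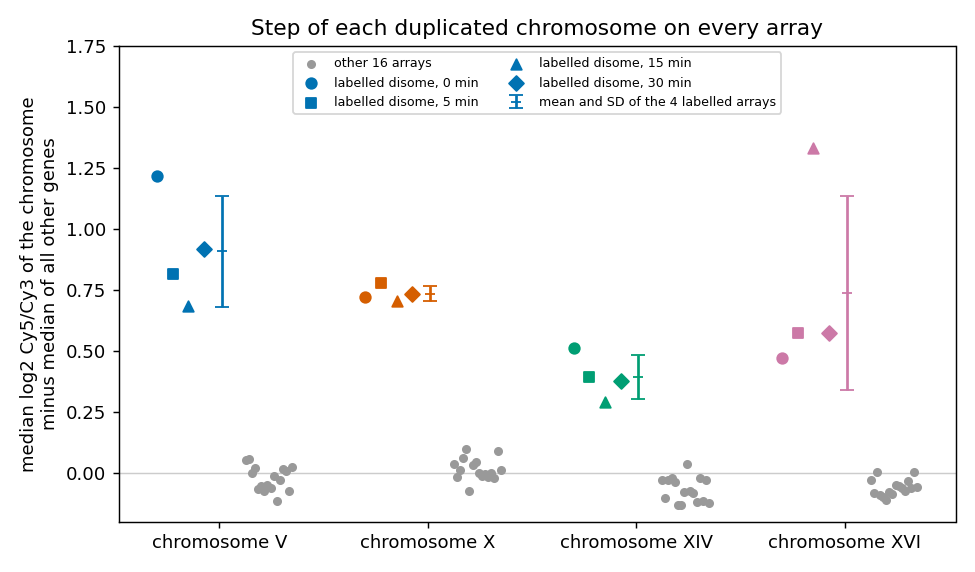
For each duplicated chromosome, the vertical axis gives the median log2 Cy5/Cy3 of its genes minus that of all other genes on every array; coloured markers are the 4 arrays of the labelled disome (shape gives the time), bars their mean and SD, and grey points the other 16 arrays. The labelled arrays lie between 0.29 and 1.33 and stand above the grey points of the same chromosome.

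Within 5 min at 37 °C, genes of chaperones, the general stress response and reserve carbohydrate metabolism rose. PGM2 (YMR105C), a phosphoglucomutase that supplies trehalose and glycogen synthesis, rose by 4.58 ± 1.02 on the log2 scale (SD over 5 strains; limma adjusted p = 0.000208). CIN5 (YOR028C), a transcription factor of the stress response, rose by 4.38 ± 0.88, and RTC3 (YHR087W), a stress-induced protein, by 4.30 ± 1.24. The largest falls were in REI1 (YBR267W), a factor of cytoplasmic ribosome assembly, at −3.64 ± 0.98, in RRN11 (YML043C), a component of the RNA polymerase I core factor, at −3.58 ± 0.55, and in HMT1 (YBR034C), a protein arginine methyltransferase, at −3.44 ± 0.80. All 6 moved the same way in 5 of 5 strains, as the rule for naming them required.

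Of 22 Hsf1 chaperones, the targets of the heat shock transcription factor, 18 rose, 0 fell and 4 did not pass at 5 min, or 21 rose when adjusted over the list alone. CUR1, which sorts misfolded proteins, rose by 3.33 ± 0.85 (5 of 5 strains), and FES1, a nucleotide exchange factor of Hsp70, by 2.27 ± 1.16. HSP104, SSA4, HSP82, HSP42 and BTN2 were saturated in Cy5 on all 5 arrays at 5 min, so their sizes are bounds or are not given. Against the 5 arrays at 0 min, the disaggregase HSP104 rose at least 5.89-fold (adjusted p = 0.0107), the Hsp90 HSP82 at least 3.73-fold (0.0033) and the sorting factor BTN2 at least 5.65-fold (0.00157). The Hsp70 SSA4 (0.0171) and the small chaperone HSP42 (0.00222) also rose, with no size given. For SSA4 the Cy5 value lay above the fitted ratio, and for HSP42 1 array at 0 min was saturated too. The fold bounds come from the Cy5 channel after loess and between-array scaling and are open to dye bias, since no dyes were swapped.

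Of 23 Msn2/4 general stress genes, 17 rose at 5 min and 0 fell, or 18 rose when adjusted over the list alone. HXK1, a hexokinase, rose by 3.99 ± 0.94, the catalase CTT1 by 3.60 ± 1.16, the membrane-associated HSP12 by 3.13 ± 0.64 and the small chaperone HSP26 by 3.54 ± 1.29, each in 5 of 5 strains. Of 16 trehalose and glycogen genes 14 rose, or 15 adjusted over the list alone, with the glycogen synthase GSY1 at 4.22 ± 0.80 and the glycogen phosphorylase GPH1 at 3.37 ± 1.17. Camera with a preset correlation gave adjusted p = 7.55e-14 for the Hsf1 chaperones, 1.64e-16 for the Msn2/4 genes and 1.46e-10 for trehalose and glycogen. Each of these lists had adjusted p = 0.136 with an estimated correlation. Ribosome biogenesis genes had a median of −1.15, and 5 of 61 fell (4 adjusted over the list alone; camera adjusted p = 2.11e-09), among them NOG2 at −3.12 ± 0.43 (n = 4). Of the RNA polymerase I and III subunits 4 of 19 fell (5 over the list alone; camera adjusted p = 0.000322), and for both of these lists camera gave adjusted p = 0.742 with an estimated correlation.

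Other lists held few called genes at 5 min. In oxidative stress defence 3 of 16 rose (5 adjusted over the list alone), among them the peroxiredoxin PRX1 at 2.36 ± 0.59 and the superoxide dismutase SOD2 at 1.06 ± 0.30, with a camera adjusted p of 0.00214 and adjusted p = 0.426 with an estimated correlation. RPN4, the transcription factor of the proteasome genes, rose by 2.42 ± 0.55 and was the only one of 35 proteasome genes to pass (camera adjusted p = 0.208). The pheromone-responsive cell cycle inhibitor FAR1 fell by 1.81 on the log2 scale (SD 0.75, 5 of 5 strains), and the cyclin PCL1 by 1.38 (SD 0.59), which was 1 of 2 genes of 17 to fall in the G1/S list (1 over the list alone; camera adjusted p = 0.0887). Median, mean and camera direction differed in sign at 5 min for the iron regulon (−0.04, 0.11, down) and Gcn4 amino acid synthesis (0.14, 0.04, down), neither of which passed camera.

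In limma's fit over all 20 arrays, 885 of 6231 genes passed at 5 min (559 rose, 326 fell), 493 of them by at least 2-fold. Median centring in place of loess left 264 genes, and leaving out disome XIV left 368. The 8 arrays of X and XIV called 906 genes. The 12 arrays of WT, V and XVI, which include all 5 dim or noisy arrays, called 8, and the 15 arrays left without those 5 called 2152.

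After 15 min, genes of ribosome production fell in all 5 strains while stress and carbohydrate genes stayed high. BRX1 (YOL077C), DBP3 (YGL078C), NOP15 (YNL110C), SPB1 (YCL054W) and CIC1 (YHR052W), all assembly factors of the large ribosomal subunit, stood at −4.19 ± 2.35, −4.10 ± 1.80, −4.09 ± 1.54, −4.05 ± 2.34 and −4.04 ± 1.30. RPA34 (YJL148W), a subunit of RNA polymerase I, fell by 3.92 on the log2 scale (SD 1.46, limma adjusted p = 0.000447, 5 of 5 strains, as the rule for naming required). Among the rises, CYB2 (YML054C), the lactate dehydrogenase of mitochondria, stood at 4.10 ± 1.94 and PGM2 at 3.90 ± 1.89. SOL4 (YGR248W), of the pentose phosphate pathway, stood at 3.70 ± 1.68, the glutamate decarboxylase GAD1 (YMR250W) at 3.62 ± 1.77, the protease inhibitor TFS1 (YLR178C) at 3.57 ± 1.45 and TMA10 (YLR327C), which associates with ribosomes, at 3.52 ± 1.44. For BRX1 the dim 15 min array of disome XVI gave a response of −0.09, against −5.95 to −4.54 in the other strains.

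All 61 ribosome biogenesis genes fell at 15 min, also when adjusted over the list alone, with a median of −3.01. NOP1, which methylates ribosomal RNA, stood at −3.75 ± 1.11 and NOP56, of the same particle, at −3.83 ± 1.28. Of 19 RNA polymerase I and III subunits 18 fell (19 adjusted over the list alone), with the polymerase III subunit RPO31 at −2.16 ± 0.60 and the shared subunit RPC40 at −2.92 ± 0.72. Of 137 cytosolic ribosomal protein genes 92 fell and 0 rose (101 fell adjusted over the list alone), with RPL20B at −3.07 ± 0.96 and RPS7B at −2.78 ± 1.07. Camera gave adjusted p = 2.05e-23, 7.96e-10 and 7.36e-18 for these 3 lists in that order, and adjusted p = 0.320, 0.320 and 0.339 with an estimated correlation.

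All 16 trehalose and glycogen genes rose at 15 min, and 22 of 23 Msn2/4 genes and 17 of 22 Hsf1 chaperones did; adjusted over the list alone the counts were 16, 22 and 20. GPH1 stood at 2.96 ± 0.78, the trehalose phosphate synthase TPS1 at 2.36 ± 1.20, the aldehyde dehydrogenase ALD3 at 2.94 ± 0.63 and CUR1 at 2.08 ± 1.07. HSP104 did not pass at 15 min (1.68 ± 1.86, adjusted p = 0.0771, positive in 3 of 5 strains). SSA4 rose by 2.48 (SE 0.708), HSP82 by 2.23 ± 1.27, HSP42 by 2.57 ± 1.28, BTN2 by 1.87 ± 1.21, HSP26 by 3.40 ± 1.57, CTT1 by 2.82 ± 1.43 and HSP12 by 3.57 ± 2.30 (4 of 5 strains). The sizes for SSA4 and HSP26 are uncertain, because both were saturated in Cy5 on 4 of 5 arrays at 15 min. Camera gave adjusted p = 3.84e-07 for trehalose and glycogen, 1.95e-13 for Msn2/4 and 3.84e-07 for Hsf1, and adjusted p = 0.320, 0.243 and 0.320 with an estimated correlation.

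Respiratory genes rose in part at 15 min: of 41 genes of the TCA cycle and respiration 17 rose and 1 fell (22 and 1 adjusted over the list alone), with the malate dehydrogenase MDH1 at 1.76 ± 0.73 and the succinate dehydrogenase subunit SDH2 at 1.23 ± 0.56. Oxidative stress defence had 7 rises among 16 genes (7 over the list alone), with PRX1 at 2.49 ± 1.32, and the unfolded protein response of the endoplasmic reticulum 7 among 14 (7 over the list alone), with the ubiquitin ligase HRD1 at 1.53 ± 0.39. Of 35 proteasome genes 5 rose (4 over the list alone), with RPN4 at 1.65 ± 1.09. Their camera adjusted p was 5.63e-05, 0.00165, 0.00796 and 0.000587 in that order, and adjusted p = 0.442, 0.320, 0.363 and 0.442 with an estimated correlation. In the G1/S list 9 of 17 genes fell (9 over the list alone), with the ribonucleotide reductase RNR1 at −2.11 ± 0.80 and the DNA polymerase POL2 at −0.91 ± 0.26, and camera gave adjusted p = 0.0017 and adjusted p = 0.243 with an estimated correlation.

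Phosphate regulon genes fell in 3 of 12 cases at 15 min (3 over the list alone), with the regulator PHO81 at −0.84 ± 0.59, a camera adjusted p of 0.0204 and adjusted p = 0.565 with an estimated correlation. The remaining 12 lists did not pass camera at 15 min. Adjusted over the list alone they had the same counts of rises and falls as over all genes, except in the iron and a-specific lists. Gcn4 amino acid synthesis had 1 rise and 6 falls among 21 genes, with the lysine gene LYS20 at −1.38 ± 0.29. In the iron regulon 4 of 15 rose and 1 fell (5 and 1 over the list alone), with the heme oxygenase HMX1 at 1.95 ± 1.45, and in cell wall integrity 2 of 11 rose and 1 fell, with PST1 at 1.14 ± 0.62. Ergosterol synthesis had 4 falls among 23, with ERG11 at −0.99 ± 0.39, daughter cell separation 4 among 8, with the glucanase DSE2 at −1.11 ± 0.80, and methionine and sulfur 1 among 15, SAM1 at −2.27 ± 1.45. Glycolysis had 1 rise among 16, TDH1 at 0.78 ± 0.64, and a list median of 0.11 that turned negative under median centring, with Agilent's processed signals and in the value table. Among cell type markers, 1 of 7 a-specific genes fell (0 over the list alone), the receptor STE2 at −0.74 ± 0.69. Of the haploid-specific genes 2 of 7 fell, FAR1 at −1.83 ± 0.43 and STE4 at −1.29 ± 0.91, and of the sporulation genes 1 of 10 rose, IME2, and 2 fell, with a median of 0.15, a mean of −0.02 and an upward camera direction. None of the 8 histone genes or the 4 alpha-specific genes passed.

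The fit called 2196 of 6231 genes at 15 min (1037 rose, 1159 fell), 1243 of them by at least 2-fold. Median centring left 1202 and leaving out disome XIV left 1021. The arrays of X and XIV called 3103 genes, those of WT, V and XVI, with all 5 dim or noisy arrays among them, 3, and all arrays but those 5 called 3585.

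**Figure D3:**
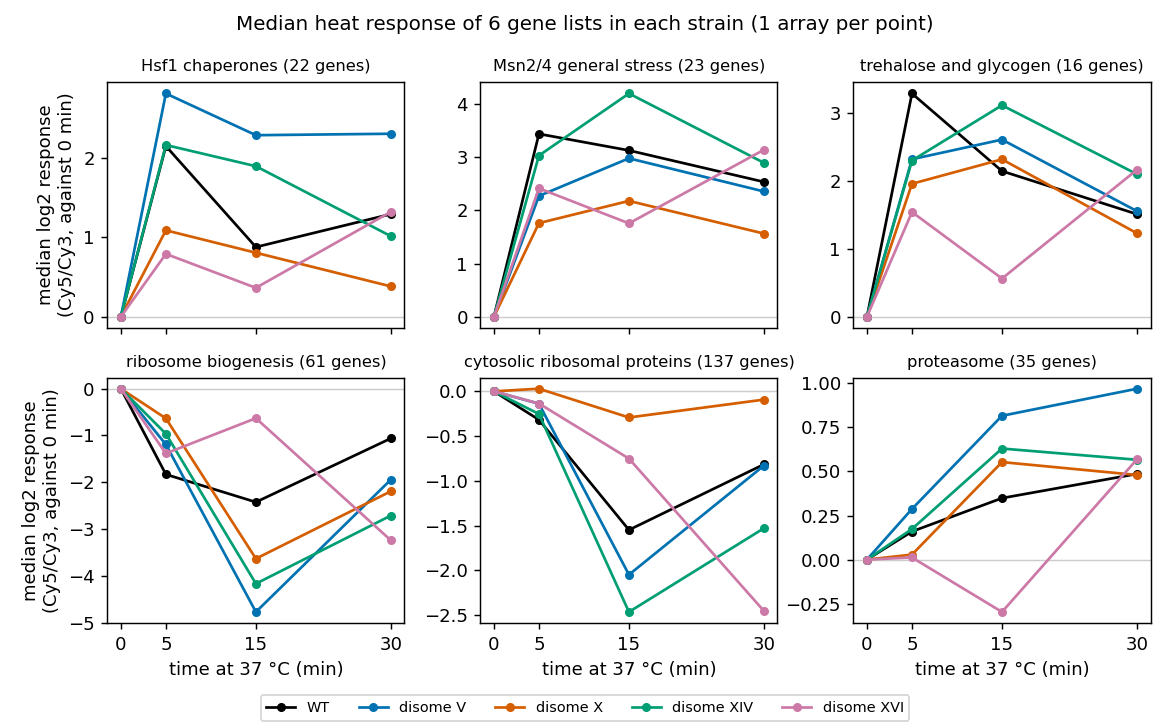
Each panel gives, for 1 gene list, the median log2 Cy5/Cy3 response of its genes against the 0 min array of the same strain, over the time at 37 °C in minutes; each line is a strain and each point 1 array. Ribosome biogenesis reached −4.77 in disome V at 15 min and −0.63 in disome XVI, and the Msn2/4 list lay between 1.76 and 4.20 at that time.

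At 30 min general stress genes were higher than before heating and genes of ribosome production were lower. HSP26 rose by 3.95 ± 1.90 (adjusted p = 0.00128), HSP12 by 3.79 ± 1.30 and PGM2 by 3.61 ± 0.74, and DBP2 (YNL112W), an RNA helicase, stood at −3.46 ± 1.17. DHR2 (YKL078W) and HCA4 (YJL033W), helicases of small subunit processing, stood at −3.29 ± 1.60 and −3.26 ± 1.07. These 6 genes moved the same way in 5 of 5 strains, as the rule for naming them required. SSA4 rose by 3.28 ± 1.84, CTT1 by 2.53 ± 1.42, HSP82 by 2.01 ± 1.34 and HSP42 by 1.65 ± 1.13 (4 of 5 strains). HSP104 at 1.81 ± 1.58 (adjusted p = 0.0845) and BTN2 at 1.32 ± 1.07 (0.0867) did not pass.

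Of 35 proteasome genes 14 rose at 30 min and 0 fell (21 adjusted over the list alone), with the core subunits PRE1 at 0.68 ± 0.25 and SCL1 at 0.81 ± 0.51. In the unfolded protein response 6 of 14 rose (9 over the list alone), in oxidative stress defence 5 of 16 (6 over the list alone) and in cell wall integrity 3 of 11 (5 over the list alone), with PST1 at 1.74 ± 0.46 and the kinase SLT2 at 0.92 ± 0.34. Camera gave adjusted p = 1.71e-09, 5.3e-05, 0.000325 and 0.0117 for these 4 lists, each with adjusted p = 0.247 with an estimated correlation. The Hsf1 list had 11 rises of 22 (17 over the list alone; HSP10 at 2.38 ± 1.28), the Msn2/4 list 18 of 23 (20; TFS1 at 3.48 ± 0.78) and trehalose and glycogen 11 of 16 (14; GPH1 at 2.91 ± 0.29). Camera adjusted p was 7.26e-08, 1.15e-16 and 5.49e-07, and adjusted p = 0.247, 0.174 and 0.247 with an estimated correlation.

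Ribosome biogenesis genes fell in 46 of 61 cases at 30 min (57 over the list alone; NOP1 at −2.60 ± 0.54), ribosomal proteins in 46 of 137 (68; RPL20B at −2.27 ± 1.24) and polymerase subunits in 11 of 19 (15; RPC40 at −2.12 ± 0.66). Camera adjusted p was 5.33e-21, 9.53e-18 and 7.89e-08, and adjusted p = 0.247, 0.279 and 0.247 with an estimated correlation. The histones HTB2 at −1.44 (SE 0.320) and HHT1 at −1.04 ± 0.91 fell, each negative in 4 of 5 strains and 2 of 8 (2 over the list alone), with a camera adjusted p of 0.0366 and adjusted p = 0.369 with an estimated correlation. Glycolysis passed camera upward (adjusted p = 0.0375, and adjusted p = 0.461 with an estimated correlation), but its median of 0.44 became −0.51 under median centring, −0.37 with Agilent's processed signals and −0.29 in the value table. For TDH1 itself, which rose by 0.88 ± 0.65, the estimate under median centring was −0.00. Daughter cell separation had a median of −0.03 and a mean of −0.02 with an upward camera direction that did not pass.

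At 30 min 1166 of 6231 genes passed (557 rose, 609 fell), 671 by at least 2-fold. The balance moved with the scaling: 119 rose and 411 fell under median centring, 204 and 515 with Agilent's processed signals, and 199 and 541 in the value table. Without disome XIV 160 genes passed, on X and XIV alone 2045, on WT, V and XVI alone 5, and without the 5 dim or noisy arrays, which all lie in that last set, 2964.

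**Figure D4:**
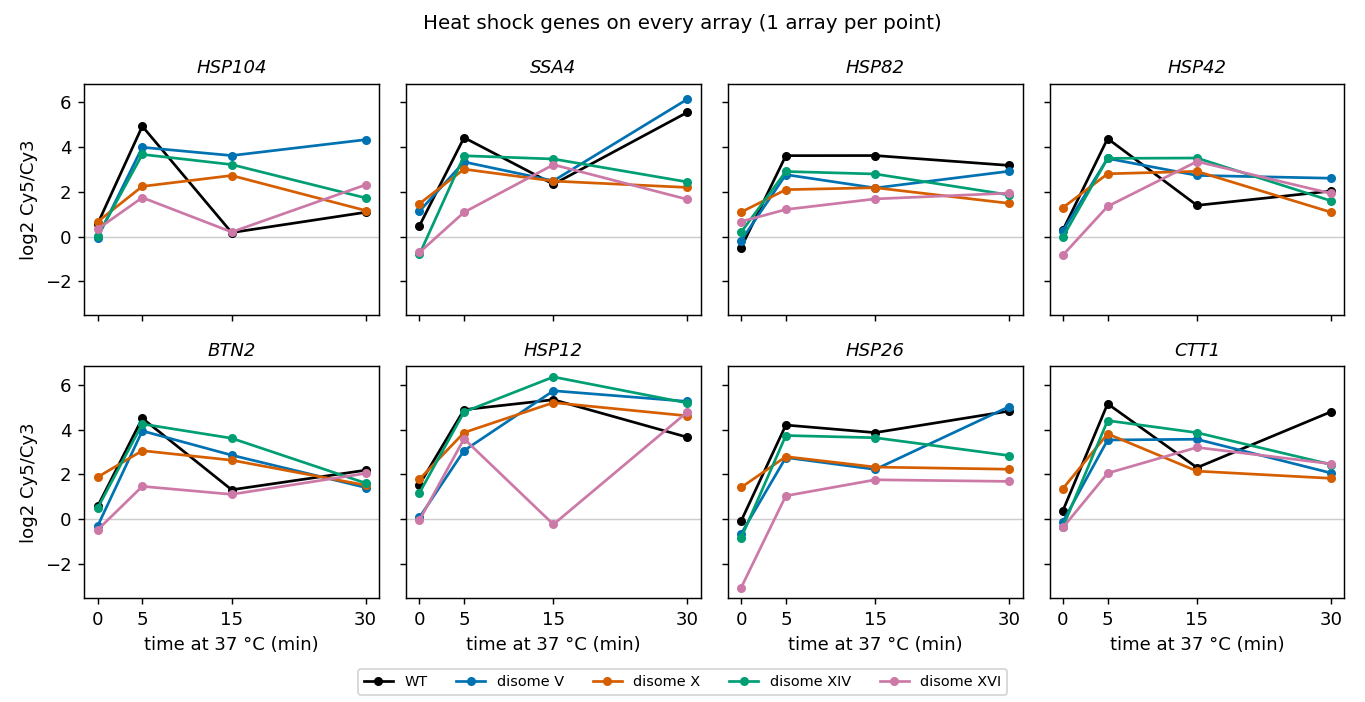
Log2 Cy5/Cy3 of 8 heat shock genes against time at 37 °C in minutes, with 1 line per strain and 1 array per point. At 5 min HSP104, SSA4, HSP82, HSP42 and BTN2 were saturated in Cy5 on all 5 arrays, so those points are lower bounds; HSP104 in WT and disome XVI returned near 0 on the dim arrays at 15 min.

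Outside its duplicated chromosome, disome V differed from WT in 3 genes. ELO1 (YJL196C), a fatty acid elongase, was higher by 1.30 ± 0.11 (SD over 4 times; limma adjusted p = 0.00861) and DAL5 (YJR152W), an allantoate permease, by 1.30 ± 0.88 (0.033). The mitochondrially encoded ATP6 (Q0085), a subunit of the ATP synthase, was higher by 4.29 (SE 0.895, 0.0351). Its log2 Cy5/Cy3 was 7.92 and 5.79 on the dim arrays at 0 and 30 min, where the median of 23 mitochondrial genes was 5.91 and 3.10, and 2.07 and 1.32 at 5 and 15 min. All 3 were higher at 4 of 4 times. In the fixed lists only genes of chromosome V itself passed: the proteasome genes PUP3 and RPN3 and the tryptophan gene TRP2, at 1.23 ± 0.49, 1.20 ± 0.51 and 1.14 ± 0.20. Adjusted over the list alone, 3 of 35 proteasome and 5 of 21 Gcn4 genes were higher, and 0 of 61 ribosome biogenesis genes were lower. These counts include genes of chromosome V. The Hsf1 chaperones had a median of −0.02 and a mean of 0.07 and did not pass camera.

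Camera, which kept genes of chromosome V in the lists, called 3 lists higher and 5 lower in disome V, none with an estimated correlation. Ribosome biogenesis had a median of −0.96 (camera adjusted p = 3.52e-08) and the Gcn4 list a median of 0.53 (3.93e-05), each with adjusted p = 0.877 with an estimated correlation. Glycolysis and ergosterol synthesis, with medians of 0.36 and 0.26, turned negative under median centring, with Agilent's processed signals and in the value table, at −0.69, −0.65 and −0.63 for the former and −0.26, −0.36 and −0.33 for the latter. The count of 3 among 5946 genes, with 455 at an unadjusted p under 0.05, became 0 without the 0 min arrays, on the 12 arrays of WT, V and XVI, and in Cy5 alone. It was 60 with array quality weights and 20 without the 5 dim or noisy arrays.

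Among the genes that differed most between disome X and WT were single genes of purine, lysine and heme synthesis, iron uptake and phosphate supply. ADE1 (YAR015W), of purine synthesis, was higher by 4.60 ± 0.33 (adjusted p = 0.00283), LYS2 (YBR115C), of lysine synthesis, by 3.03 ± 0.21 (0.00404) and FET3 (YMR058W), the iron oxidase of high-affinity uptake, by 3.09 ± 0.96 (0.00587). GIT1 (YCR098C), a glycerophosphoinositol permease, stood at −3.48 ± 1.24 (0.00368), the acid phosphatase PHO5 (YBR093C) at −3.13 ± 1.32 (0.0375) and HEM13 (YDR044W), of heme synthesis, at −2.88 ± 1.12 (0.0106). Each difference had its sign at 4 of 4 times. The common reference was WT RNA, and ADE1 stood between −0.05 and 0.22 on the 4 WT arrays. Each disome is a single strain, so an effect of its extra chromosome cannot be told apart from any other genotype difference from WT.

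In disome X, counting list members on the duplicated chromosome too, 1 of 12 phosphate regulon genes was higher and 4 were lower (1 and 7 adjusted over the list alone). SPL2, a regulator of phosphate uptake, stood at −2.72 ± 0.73, the polyphosphate synthesis gene VTC3 at −2.14 ± 0.83, and PHO86, which lies on chromosome X, at 0.81 ± 0.14. Of 15 iron regulon genes 3 were higher (6 over the list alone), with the permease FTR1 at 1.99 ± 0.36 and the reductase FRE1 at 1.44 ± 0.86. In oxidative stress defence 2 of 16 were higher (2 over the list alone), the peroxidase GPX2 at 1.27 ± 0.28 and OYE3 at 1.76 ± 0.25. Camera adjusted p was 0.00027 for the phosphate list, 0.00393 for the iron list and 0.187 for oxidative stress defence, each with adjusted p = 0.772 with an estimated correlation. The iron list's median of 0.73 became −0.05 in the value table, where the median over all genes was −0.13. Of 137 ribosomal protein genes 2 were higher (0 over the list alone; camera adjusted p = 0.00027, and adjusted p = 0.772 with an estimated correlation). These were RPL43A (adjusted p = 0.0468) and RPL30 (0.0487), saturated on all 4 disome X arrays and 1 of 4 WT arrays, so no size is given. In Cy5 alone RPL43A stood at −0.38 and RPL30 at −0.46. Cy5 after loess and between-array scaling was instead higher by 0.56 and 0.63, so these capped values cannot settle the direction. HSP60, a mitochondrial chaperonin, and PGI1, of glycolysis, passed as lower (limma adjusted p = 0.0102 and 0.0252). They were saturated on all 4 disome X arrays and on 2 and 1 of 4 WT arrays. Capped Cy5 values can themselves lower the ratio, so no size is given and the direction is not settled.

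Outside chromosome X, 164 of 5850 genes passed (70 higher, 94 lower; 78 by at least 2-fold). With Agilent's processed signals 37 were higher and 23 lower, in the deposited values 4 were higher and 10 lower, and 0 genes passed without the 5 min arrays or in Cy5 alone. With array quality weights 716 genes passed, and without the 5 dim or noisy arrays 1676 (841 higher, 835 lower). The arrays of WT and disome X lie in different Cy3 profiles, so the profile and the strain cannot be told apart in the ratio: Cy3 alone called 2541 genes.

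Disome XIV showed the widest difference from WT, again with ADE1 at 4.87 ± 0.21 (adjusted p = 0.000623) and LYS2 at 3.04 ± 0.59 (0.00181) among the highest. The mitochondrially encoded OLI1 (Q0130), an ATP synthase subunit, stood at 3.58 ± 1.87 (0.034). HEM13 stood at −3.61 ± 0.86 (0.00138), PRY1 (YJL079C), a sterol-binding secreted protein, at −2.82 ± 0.82 (0.000234) and the CTP synthase URA7 (YBL039C) at −2.65 ± 1.40 (0.0229), each with its sign at 4 of 4 times.

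The list counts and camera for disome XIV include list members on the duplicated chromosome. Proteasome genes were higher in 9 of 35 cases in disome XIV and lower in 0 (11 adjusted over the list alone), with PRE9 at 1.12 ± 0.27 and PRE1 at 0.85 ± 0.36. In the iron regulon 5 of 15 were higher and 1 lower (7 and 1 over the list alone), with FET3 at 2.44 ± 1.39, the siderophore transporter SIT1 at 1.94 ± 0.88 and the mannoprotein FIT1 at −1.22 ± 0.52. Camera adjusted p was 0.000353 and 0.00954, each with adjusted p = 0.987 with an estimated correlation. Of 23 ergosterol genes 2 were higher and 6 lower (2 and 6 over the list alone), with ERG5 at −2.08 ± 0.79, NCP1 at −1.61 ± 0.63 and ERG2 at 1.34 ± 0.81 (camera adjusted p = 0.278). In daughter cell separation 1 of 8 was higher and 4 lower (1 and 4 over the list alone; camera adjusted p = 0.553), with the chitinase CTS1 at −1.17 ± 0.71. Of 7 haploid-specific genes 2 were lower (5 over the list alone), FAR1 at −1.64 ± 0.75 and the kinase FUS3 at −0.75 ± 0.38, with a camera adjusted p of 0.0473 and adjusted p = 0.522 with an estimated correlation. Ribosomal protein genes went both ways, with 3 of 137 higher and 5 lower (0 and 4 over the list alone), a median of 0.07 and a mean of −0.08 (camera adjusted p = 0.903). In cell wall integrity the glucan synthase FKS1 stood at −1.88 ± 0.68, in a list with 1 higher and 2 lower of 11 (1 and 2 over the list alone; camera adjusted p = 0.86).

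Outside chromosome XIV, 919 of 5812 genes passed (388 higher, 531 lower; 460 by at least 2-fold). The balance was 30 higher and 156 lower under median centring, 99 and 209 with Agilent's processed signals, and 32 and 236 in the value table, and 104 genes passed without the 5 min arrays. With array quality weights 1760 genes passed, and without the 5 dim or noisy arrays 2207 (1054 higher, 1153 lower). In Cy5 alone the direction turned for URA7 at 1.02, NCP1 at 0.95, CTS1 at 0.20 and FUS3 at 0.48. Disome XIV shares the Cy3 profile of disome X: Cy3 alone called 2441 genes and Cy5 alone 0.

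Disome XVI differed from WT in 4 genes outside its chromosome, all lower. HSP26, the small chaperone, stood at −2.84 ± 0.50 (adjusted p = 0.0394), the mitochondrial aldehyde dehydrogenase ALD4 (YOR374W) at −2.02 ± 1.12 (0.0396) and the drug exporter YOR1 (YGR281W) at −1.19 ± 0.93 (0.0449), each lower at 4 of 4 times. The remaining gene, named after its value was seen, was MGA2 (YIR033W), a membrane-bound regulator of fatty acid desaturation, at −0.83 (SE 0.166, 0.0248). In the fixed lists, 0 of 22 Hsf1 chaperones and 1 of 23 Msn2/4 genes, HSP26, passed (0 and 2 adjusted over the list alone), though their medians were −0.67 and −0.93. The proteasome subunit RPN7, a chromosome XVI gene, was higher by 0.96 ± 0.30, and 0 of 12 phosphate regulon genes passed (3 lower over the list alone). Oxidative stress defence had a median of −0.09 and a mean of −0.01 with an upward camera direction that did not pass.

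Camera, which kept genes of chromosome XVI in the lists, called 2 lists higher and 8 lower in disome XVI, none with an estimated correlation. Adjusted p was 3.26e-06 for the Hsf1 list and 6.98e-08 for the Msn2/4 list, and adjusted p = 0.551 and 0.536 with an estimated correlation. The 4 calls among 5739 genes, with 256 at an unadjusted p under 0.05, became 1 higher and 0 lower under median centring and in the value table and 2 higher and 0 lower with Agilent's processed signals, and 0 genes passed on the 12 arrays of WT, V and XVI, in Cy5 alone or without the 0 min arrays. Array quality weights gave 10 calls, and leaving out the 5 dim or noisy arrays gave 11.

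Taking the 4 disomes as a group against WT, 3 of 4654 genes outside the 4 chromosomes passed. ADE1 was higher by 3.50 (SE 0.519, limma adjusted p = 0.0218) and LYS2 by 2.40 (SE 0.396, 0.0372), and STT4 (YLR305C), a phosphatidylinositol kinase, stood at −0.74 (SE 0.123, 0.0372). Each had the same sign in all 4 disomes, as the rule for naming them required. WT is a single strain, so an effect of the extra chromosomes cannot be told apart from another genotype difference between WT and the disomes. ADE1 and LYS2 were not uniform within each disome. On disome V at 0 min they stood at 0.08 and 0.28, and on disome XVI at 15 min at 0.21 and −0.10. The other 14 disomic arrays gave ADE1 1.51 to 5.15. The fixed lists kept genes of the 4 chromosomes. In them the only gene to pass was LYS2, 1 of 21 Gcn4 genes (2 over the list alone, camera adjusted p = 0.015, and adjusted p = 0.974 with an estimated correlation). Phosphate regulon genes had a median of −0.88 and iron regulon genes of 0.40, with 0 of 12 and 0 of 15 passing (4 lower and 3 higher over the list alone), camera adjusted p of 2.03e-05 and 0.000591, and adjusted p = 0.501 with an estimated correlation for each. Proteasome genes had a median of 0.15 (camera adjusted p = 0.0127, and adjusted p = 0.974 with an estimated correlation), which was −0.04 under median centring, −0.01 with Agilent's processed signals and −0.14 in the value table. The median over all genes was −0.06, 0.01 and −0.05 in these settings and 0.01 in the main one. With 553 genes at an unadjusted p under 0.05, the count by direction was 2 higher and 1 lower, against 2 and 0 under median centring and with Agilent's processed signals, 1 and 0 in the value table, and 0 without the 0 min arrays or with the strict filter on dim probes. Without the 5 dim or noisy arrays the count was 30 higher and 71 lower, and with array quality weights 2 and 3.

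The heat responses of the disomes and of WT were positively correlated across genes. At 15 min the log2 response of each disome correlated with that of WT at r = 0.49 (V), 0.71 (X), 0.73 (XIV) and 0.29 (XVI), a mean of 0.56 (SD 0.21, n = 4 disomes) over 6006 genes, with a mean Spearman correlation of 0.50. At 5 min r was 0.39, 0.79, 0.77 and 0.58 in the same order, and at 30 min it was 0.13, 0.37, 0.30 and 0.30. The WT arrays at 15 and 30 min, the disome V arrays at 0 and 30 min and the disome XVI array at 15 min were the dim or noisy ones. The 0 min array of disome V enters all its responses. It was like the disome XVI array at 15 min (r = 0.80 after loess), and the 15 min responses of V and XVI take these arrays with opposite signs. Genes are not independent replicates, so no p-value is given, and in Cy5 alone the mean at 15 min was 0.27. Between pairs of disomes, which share no array, r averaged 0.65 at 5 min, 0.39 at 15 min (lowest −0.36, highest 0.89) and 0.68 at 30 min over 6 pairs.

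Gene by gene, no difference between the disomic and the WT response passed. Limma called 0 genes at 5, 15 and 30 min, with 113, 249 and 340 at an unadjusted p under 0.05, and 0 with trend and robust moderation. Differences (disomes minus WT), none past the threshold, were at 15 min 2.58 for HSP104, 0.78 for SSA4, −2.34 for HSP82, −0.27 for HSP12, −0.67 for HSP26, 1.14 for CTT1, 1.41 for BTN2 and 1.84 for HSP42. At 30 min they were 1.62, −2.23, −2.06, 2.10, −1.18, −2.34, −0.36 and −0.11 in the same order. At 5 min HSP12, HSP26 and CTT1 had −0.26, −0.92 and −1.45, and the other 5 were saturated on all arrays. At 15 min SSA4 and HSP26 were saturated in Cy5 on 4 of 5 arrays, so these sizes are uncertain. WT has 1 array per time, assumed to vary like the disomes, and at 15 min, the time simulated, this test recovered 0, 16, 44 and 68% of genes changed by 1, 2, 3 and 4 log2 units. The simulation gave all arrays the same noise, whereas the WT array at 15 min is a dim or noisy one, so the real recovery may differ. Leaving out disome XVI gave 74 genes at 15 min, Agilent's processed signals 8, and Cy5 alone 700 at 15 min and 305 at 30 min.

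In the tests by list too, WT has 1 array per time, and at 15 and 30 min that array is dim or noisy. Camera at 5 min called 6 lists with a higher and 4 with a lower response in the disomes. Among the latter were the Hsf1 chaperones with a median of −1.03 (adjusted p = 1.26e-05) and trehalose and glycogen with −1.09 (0.000619). For Hsf1 this rested on disomes X and XVI, at 1.09 and 0.79 against 2.15 in WT, while V and XIV gave 2.81 and 2.16. Cy5 was saturated at 5 min on 669 spots in X and 895 in XVI, against 90 in WT, 217 in V and 287 in XIV. HSP104, SSA4, HSP82, HSP42 and BTN2 of this list were saturated on every array at 5 min. Capped values can lower a heat response, so this difference may partly reflect the scanner's ceiling. For trehalose and glycogen all 4 disomes lay between 1.54 and 2.32, below 3.29 in WT. Of either list 0 genes passed, and each had adjusted p = 0.572 with an estimated correlation. At 30 min 2 lists were lower, ribosome biogenesis with −1.36 (adjusted p = 6.34e-05, and adjusted p = 0.879 with an estimated correlation) and ribosomal proteins with −0.50 (0.0306, and again adjusted p = 0.879 with an estimated correlation). Ribosomal proteins were lower than in WT (−0.82) in disomes XIV (−1.53) and XVI (−2.45), near it in V (−0.83) and higher in X (−0.09). Both list medians changed sign with the scaling. Ribosome biogenesis went to 0.16 under median centring, 0.17 with Agilent's processed signals and 0.49 in the value table. Ribosomal proteins went to 0.68, 0.36 and 0.44. The median over all genes was 0.12, 0.17 and 0.36 in those settings and −0.05 in the main one. Ribosome biogenesis thus lay near all genes under median centring and with Agilent's processed signals. At 15 min glycolysis was higher at 0.70 and ribosome biogenesis lower at −0.75 (adjusted p = 0.0381 and 0.0334, and adjusted p = 0.841 with an estimated correlation), but glycolysis stood at −1.74 under median centring and ribosome biogenesis at 1.53 in the value table. Median and mean differed in sign for cell wall integrity at 15 min (−0.05 and 0.32) and for the Hsf1 chaperones at 30 min (−0.10 and 0.11), and neither passed camera.

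The unheated difference of each disome from WT was compared with the mean 15 min heat response of the other 3 disomes, which shares no array with it, over genes on none of the 4 chromosomes. At 15 min the correlation across genes was 0.32 for disome V (Spearman 0.33), −0.07 for X (−0.11), −0.05 for XIV (−0.06) and −0.09 for XVI (−0.09). For disome V the value came from disome XVI, with r of 0.81, and not from disomes X or XIV, at 0.07 and −0.06. With the 5 or 30 min response in its place the value for disome V was −0.0946 or −0.0725, and under median centring it was 0.70. For disome XVI it changed sign to 0.03 under median centring and was −0.23 with Agilent's processed signals.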

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

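The tests of the dyes, of the dim samples and of a heat response in unheated disome V were chosen only after the result was seen, as were Cy5 alone and the splits within strain or time; the tests of the reference channel, of a batch in Cy5, of genomic DNA and of all other splits of the arrays were planned before.

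A sample far from the others of its group was looked for in 122 sets of 4 or 5 arrays, of which 7 held one, against 6.1 expected by chance at 1 in 20. Chromosome XVI stood 1.33 above the rest in disome XVI at 15 min, against 0.47 to 0.57 at its other times. The proteasome response at 30 min was 0.97 in disome V and 0.48 to 0.57 elsewhere. The oxidative stress response at 5 min was 0.86 in disome V and 0.40 to 0.47 elsewhere. The methionine and sulfur response at 5 min was −0.39 in WT and 0.05 to 0.16 in the disomes. For REI1 at 5 min disome V gave −5.32 and the others −3.66 to −3.02, for BRX1 at 15 min disome XVI gave −0.0923 and the others −5.95 to −4.54, and for PGM2 at 30 min disome X gave 2.31 and the others 3.75 to 4.09.

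A difference between times appeared in 4 genes that passed limma's threshold in opposite directions at different times. They were chosen for that, so the difference between those times was bound to pass and its p-value adds nothing. HXT4, a hexose transporter, rose by 2.56 at 5 min and stood at −1.42 at 30 min, a difference of −3.98. HOF1, of cytokinesis, went from 0.70 to −0.98, a difference of −1.68, and FSH1, a serine hydrolase, from 0.69 to −0.56, a difference of −1.25. The open reading frame YHR130C went from −0.46 at 15 min to 0.48 at 30 min, a difference of 0.94. A signal in data outside the comparisons appeared in the Cy3 channel alone, which by itself called 2541 genes for disome X and 2441 for disome XIV against WT.

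The labels put the sample in Cy3, but the labelled chromosome stood farther from the rest in Cy5 alone than in Cy3 alone on 16 of 16 disomic arrays. Dyes as labelled are excluded for the disomic arrays: a common WT reference in Cy5 would not carry the extra chromosome of each strain, and in Cy3 alone its difference averaged 0.00800 (log2). An exchange of the dyes between sample and reference in the labels, with the sample in Cy5, is consistent with these values. Dyes as labelled are also excluded for the heated WT arrays, where an unheated reference would not carry the heat response: it was larger in Cy5 alone than in Cy3 alone by 2.40, 1.15 and 1.76 (log2) at 5, 15 and 30 min over 45 Hsf1 and Msn2/4 genes. For WT at 0 min no test was run, and no biological explanation was tested.

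Genes outside the extra chromosome differed from WT in disomes X and XIV, which share a Cy3 profile. Of the called genes 69.5% in X and 72.9% in XIV had the same sign in Cy5 alone, and 76.2% and 75.8% had the opposite sign in Cy3 alone. If Cy5 holds the sample and Cy3 the reference, a difference in the reference channel alone may account for part of them: over the genes called, the median share of the effect carried by Cy5 was 0.439 in disome X and 0.430 in disome XIV. For a batch shared by disomes X and XIV in the Cy5 channel, the correlation of X minus V with XIV minus XVI, with no shared array, was 0.213, between the 0.3 it needs and the 0.1 that would exclude it, so it stays open. The same correlation was 0.888 in Cy3 alone and 0.622 in the ratio, so the pattern shared by X and XIV was stronger in Cy3 than in Cy5. A biological difference of the strains stays open and untested.

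Disome V at 0 min and disome XVI at 15 min were alike (r = 0.80 after loess) and apart from the rest, with ADE1 and LYS2 near 0. The steps of the labelled chromosomes were 1.22 and 1.33, above the highest others of 0.918 and 0.574, but their spread over times depended on the scaling. The SD over the disome XVI arrays was 0.40 after loess, 0.12 under median centring and 0.15 with Agilent's processed signals. For disome V it was 0.23, 0.17 and 0.10. The steps therefore cannot decide on a dim sample that compresses ratios. A heat response in unheated disome V is argued against by correlations of 0.0727 with the response of disome X and −0.0613 with that of XIV, beside 0.81 with XVI. Genomic DNA labelled with the sample could explain high mitochondrial genes, but silent genes had Cy5 percentiles of 24.9 and 23.6 against 23.7 on the highest other array, which cannot decide it. A biological difference between these samples and the rest stays open and untested.

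Other splits of the arrays were tried on only the arrays compared. Splits that keep each strain (heat) or time (disomes) in both groups, as the fits do, number 16 for heat and 8 for each disome, too few for a share under 0.05. For heat at 5, 15 and 30 min the real splits called 1544, 997 and 1245 genes and the highest other of these 0, and for disomes X and XIV 58 and 406 against 0. Splits that also exchange arrays across strains or times reached as many genes, the real one included, in 1, 2 and 1 of 100 for heat, with highest others of 486, 1232 and 562. The 1232 came from placing WT at 0 min with the heated arrays and disome XVI at 15 min with the unheated. With the strain block, such fits compare times only within the strains that are divided between the groups. The split with 1232 thus kept the real heat contrast within disomes V, X and XIV. The split with 562 kept it within X, XIV and XVI, with its sign turned. These splits hold real heat effects and cannot gauge chance. For disomes X and XIV it was 1 and 1 of 35, highest others 0, and 3 of the 35 could not be fitted with the time block. For disomes V and XVI and all disomes the real split called 0 genes, so 35 of 35, 35 of 35 and 100 of 100 splits were bound to reach it and say nothing about chance. The highest others there, 630 genes for XVI and 726 for the split that sets the 4 disome XIV arrays apart, point to a structure of the arrays.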

How the results depend on the processing

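Tests on Cy5 alone, Cy3 over Cy5, array quality weights, without 5 doubted arrays, and on each set of strains alone were chosen only after the result was seen. Signal over background limits WT at 15 min (76.2% of Cy5 and 69.7% of Cy3 spots well above it) and at 30 min (83.4% and 88.2%); the other doubted arrays have nearly all spots above it. No replicate number pairs arrays, since each strain and time has 1. The fits pair arrays through blocks, by strain for heat and by time for disomes, and the counts without them are below. Blocks for slide and scan date were not run, because the deposited data give neither. Scaling between arrays leaves every log ratio as it was and the filter removes no gene, so neither test says anything. The brightest probe (11 results), the random strain block (3) and 5 min in place of 15 min (5) moved none beyond the counts' 1.5-fold limit or the spread between strains. Of 6588 values of named genes over all settings, 4915 kept direction and side of the threshold, 1644 fell below it and 29 reversed. Unless stated, the cause was not tested.

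Heat called 885, 2196 and 1166 genes at 5, 15 and 30 min. Median centring gave 264, 1202 and 530, Agilent's processed signals 348, 1462 and 719, the deposited values 338 and 740 at 5 and 30 min, no strain block 510 and 657, and only the arrays compared 1544 and 997 at 5 and 15 min. Cy3 alone gave 1, 0 and 0, Cy5 alone 204, 1086 and 560, array weights 2317, 4014 and 2986, and leaving out the 5 doubted arrays 2152, 3585 and 2964. Only WT, V and XVI, with all 5 doubted arrays, gave 8, 3 and 5, and only X and XIV 2045 at 30 min, with fewer arrays. Leave-one-out ranges were 368 to 1215, 1021 to 2801 and 160 to 1199, lowest without disome XIV and highest without XVI.

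Disome V (3 genes) gave 1 under median centring, 1 with Agilent's signals, 8 with offset 10, 0 in the value table, 8 in Cy3 alone, 6 with trend and robust moderation, 0 without the time block, 0 on the arrays compared, 0 in Cy5 alone, 60 with weights, 20 without the doubted arrays, 0 on WT, V and XVI, and 0 to 1 in leave-one-out. Disome X (164) gave 8, 60, 86, 14 and 2541 in the first 5 of these, 54 without the time block, 58 on the arrays compared, 0 in Cy5 alone, 716 with weights and 1676 without the doubted arrays; leave-one-out gave 0 without 5 min, 18 without 30 min, 26 without 0 min and 185 without 15 min. Disome XIV (919) gave 186 under median centring, 308 with Agilent's signals, 268 in the value table, 2441 in Cy3 alone, 374 without the time block, 406 on the arrays compared, 0 in Cy5 alone, 1760 with weights and 2207 without the doubted arrays, and 104 (without 5 min) to 811 (without 15 min). Disome XVI (4) gave 1, 2, 1, 1 and 1 in the order of disome V, 2 with trend and robust moderation, 0 without the time block, 0 on the arrays compared, 0 in Cy5 alone, 10 with weights, 11 without the doubted arrays, 0 on WT, V and XVI, and 0 to 4 in leave-one-out. All disomes (3) gave 1 in the value table, 0 with the strict filter, 2343 in Cy3 alone, 1 in Cy5 alone, 5 with weights, 101 without the doubted arrays, and 0 to 6 in leave-one-out.

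Response differences (0 at each time) gave 17 at 5 min, 4365 at 15 min and 3542 at 30 min in Cy3 alone, 700 at 15 min and 305 at 30 min in Cy5 alone, and 8 at 15 min with Agilent's signals. Leave-one-out gave 0 to 0, 0 to 74 and 0 to 0, highest without disome XVI.

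Dosage of V, X, XIV and XVI was −0.93, −0.72, −0.46 and −0.80 with Cy3 over Cy5, by construction, and −0.0611, 0.00387, 0.0647 and 0.0246 in Cy3 alone. Leave-one-out ranges were 0.83 to 0.99, 0.69 to 0.74, 0.44 to 0.50 and 0.61 to 0.89. Baseline resemblance of XVI (−0.09) was 0.0310 under median centring and −0.23 with Agilent's signals. Within the spread between strains, V (0.32) turned to −0.0946 at 5 min and −0.0725 at 30 min, X (−0.07) to 0.0204 under median centring, 0.151 in Cy3 alone and 0.0354 in Cy5 alone, and XIV (−0.05) to 0.0907 under median centring and 0.0281 without the doubted arrays. The response correlation (0.56) was 0.27 at 30 min, 0.27 in Cy5 alone, −0.0533 in Cy3 alone and 0.50 to 0.64 in leave-one-out. Of 85 calls of lists by camera, 0 passed with an estimated correlation.

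TDH1 at 30 min was −0.00263 under median centring. In Cy5 alone SIL1 at 15 min was −0.0167, KAR2 −0.55 and CCP1 −0.40, and at 30 min KAR2 was −0.14 and AHP1 −0.24. In Cy5 alone for disome X, RPL43A was −0.38, RPL30 −0.46, PHO8 1.21, ARG3 −0.31, ERG27 −0.0295 and IME1 −0.48. RPL43A and RPL30 were saturated in Cy5 on all 4 disome X arrays, so their sign is not settled. In Cy5 alone for disome XIV, URA7 was 1.02, SSA2 0.49, RPL6B 0.68, RPP2A 0.88, RPL20A 0.27, NOP1 0.15, DER1 −0.11, PHO8 1.47, SUL1 −0.34, ERG11 1.91, NCP1 0.95, DSE1 0.88, CTS1 0.20, DSE2 0.83, STE2 0.51, FUS3 0.48 and NDT80 −0.32.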

Other observations

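The contrasts between heated times were chosen only after the results against 0 min were seen, and the array compositions were also examined after the data were seen. Between 5 and 15 min, 762 genes differed in limma's fit, 226 higher and 536 lower at the later time. Between 5 and 30 min 488 differed, 156 higher and 332 lower, and between 15 and 30 min 70 differed, 38 higher and 32 lower. Ribosome biogenesis had list medians of −1.15, −3.01 and −2.18 at 5, 15 and 30 min, and cytosolic ribosomal proteins −0.13, −1.52 and −1.16. The proteasome had 0.14, 0.37 and 0.57. The differences between these list medians were not tested.

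In WT alone, the Msn2/4 list stood at 3.44, 3.13 and 2.54 at 5, 15 and 30 min, and the 4 disomes averaged 2.37 ± 0.52, 2.78 ± 1.07 and 2.49 ± 0.70. Trehalose and glycogen stood at 3.29, 2.14 and 1.51 in WT and averaged 2.03 ± 0.37, 2.15 ± 1.11 and 1.76 ± 0.45 in the disomes. WT has 1 array per time and no gene of the response difference passed.

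Mitochondrially encoded protein genes, 8 of them, had Cy5 percentiles of 99.2 in disome V at 0 min, 98.3 in disome XVI at 15 min, 93.0 in WT at 30 min and 92.7 in disome V at 30 min, and at most 39.0 on the other arrays. The Spearman correlation of Cy5 with Cy3 across genes was 0.55 on disome V at 0 min and 0.41 on disome XVI at 15 min, and 0.73 to 0.97 on the other arrays. Array quality weights, which limma estimates from the residuals, were lowest for disome XVI at 15 min (0.061) and disome V at 0 min (0.151).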
